A study of Homo sapiens with 44 samples.

How the data were processed

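Gene-level RNA-seq was measured in HCCLM3 cells after 24 h of treatment, in 44 libraries of 22 groups with 2 biological replicates each. Per the labels, RNA was extracted with the Qiagen RNeasy Plus Mini kit and libraries were made with the Hieff NGS MaxUp Dual-mode mRNA kit. The deposited table held counts, as whole numbers per gene and library, with 20263 genes under human Ensembl identifiers, of which 19757 had a gene name and 1683 were 0 in every library. The labels named the mouse builds GRCm38 and mm10, although every identifier in the table was human; the aligner, the counting tool and the annotation were not stated, so no gene positions are given. Among counts of 1 to 20, the share that was even was 62.9% to 68.1% per library, the pattern of a table that counts both mates of a read pair, so that the number of fragments is below the number of counts. Totals ran from 26060229 to 38717013 counts, and 12873 to 14049 genes had at least 10 counts in a library. Levels are CPM from edgeR with its scaling factors.

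Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, with its minimum count of 10 and minimum total of 15, which left 14922 genes and removed 5341. Library sizes were scaled by TMM. A single quasi-likelihood model with 1 mean per group was fitted to all 44 libraries with robust dispersion estimates, which gave 22 residual degrees of freedom and a biological coefficient of variation of 0.199. Fitting the groups together let 2 replicates per group borrow the spread of the others. A p-value thus rests on a pooled spread, which can understate that of a group with unlike replicates, such as TG plus ISRIB or FCCP DMSO. Each comparison was a contrast of group means with a quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within a comparison.

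The 34 comparisons were 9 of a dose against the DMSO group of its own series, 3 of the highest against the lowest dose, 10 of the highest dose with a modulator against that dose alone, 3 differences between the responses to the highest doses, 6 differences between the effects of a modulator in 2 series, and 3 between DMSO groups. Replicate numbers showed no common pairing of libraries across groups. The correlation of replicate differences between groups had a median of 0.01 in the FCCP series (range -0.13 to 0.12), -0.01 in the TG series (-0.37 to 0.24) and -0.03 in the TM series (-0.17 to 0.1). No block was therefore used in the reported values, although pairing of some groups is not excluded.

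Lists of genes were written in advance from general knowledge of the biology, 28 in all. They held ATF4 and CHOP targets; amino acid synthesis, one-carbon and transport genes; tRNA synthetases; ER chaperones; XBP1 targets of the secretory pathway; ER-associated degradation; transcripts decayed by IRE1; mitochondrial chaperones and proteases; nuclear respiratory chain genes and mitochondrial DNA genes. They also held glycolysis and hypoxia, proteasome, cytosolic heat shock, NRF2, metallothionein, autophagy and lysosome, S phase, mitosis, cell death, cholesterol, fatty acid, hepatocyte secreted protein, ribosomal protein, NF-κB, immediate early and histone genes, with stromal markers and blood and endothelial markers as signs of other cell types. Each list was tested with camera of limma 3.58.1 on voom values, with the correlation between its genes estimated and the p-values adjusted over the lists of a comparison. Of 952 such tests, 220 passed with an estimated correlation. With the preset correlation of 0.01 there were 452, which included all 220. Beside camera, members past the gene threshold were counted, over all genes and adjusted over the list alone.

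Genes were named by a fixed rule. It took, first, 10 ER stress genes for TG and TM and 14 genes for FCCP in every comparison against DMSO, whatever their result. Second, it took the 8 highest and 8 lowest log2 changes of each highest dose against DMSO, and the 4 highest and 4 lowest of each modulator comparison and each difference between series. These were drawn from called genes with a mean of at least 10 CPM in the higher group and every library of one group above every library of the other; genes without a name and pseudogenes were passed over. Last, it took up to 4 members of a described list with the smallest adjusted p, and members that went against their list. The text prints part of this selection, and list members printed outside it were chosen after their values were seen. The fold of a gene with no counts in a group was computed against a floor of 3 counts over that group. For 2 comparisons that share a group, the covariance of their log2 changes was set beside its mean in 20 simulations of unchanged groups; for 2 that share none, shared calls were set beside the number that independent lists would give.

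Alternatives planned in advance were DESeq2 1.42.0 with its Wald test, its size factors (RLE) in edgeR, no filter on low counts, a block for replicate number, only the libraries of the series concerned, the preset correlation in camera, and each of the 44 libraries left out in turn. Alternatives chosen after the data were seen were an offset for each library's trend in transcript length and GC content (natural splines with 5 degrees of freedom, values known for 14905 genes), the removal of 13 mitochondrial DNA genes, the TG DMSO group as reference for TM and FCCP doses, the TM DMSO group as reference for TG doses, and TM 1 μM as reference for the TM combinations.

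The procedure was tested on simulated data with the depth of these libraries and, for each gene, a single spread shared by all groups. Groups with unlike replicates, such as FCCP DMSO and TG plus ISRIB, were thus not imitated. The false calls below do not measure error in such groups. With 2 libraries against 2, edgeR recovered 11.9% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 77.3% of those changed 4-fold in the groups of TG with and without melatonin, with 4 false calls among 14805 genes tested. In the FCCP 5 μM and DMSO groups it recovered 7.5%, 43.3% and 83.3%, also with 4 false calls. DESeq2 recovered 19.4%, 53.7% and 81.8% with 12 false calls in the first setting. Camera recovered the 1 list changed and passed none of the others. Genes were simulated independently, so this does not measure false list calls where genes of a list vary together. No library was left out of the reported values, and all columns of the table were used.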

Results

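The data were gene-level RNA-seq read counts from HCCLM3, a human liver cancer cell line, collected 24 h after treatment. There were 44 libraries in 22 groups of 2 biological replicates. Cells in 3 series received thapsigargin (TG; 0, 0.5, 1 or 2 μM), tunicamycin (TM; 0, 0.5, 1 or 2 μM) or the mitochondrial uncoupler FCCP (0, 1.25, 2.5 or 5 μM), each series with its own DMSO group as dose 0. In 10 further groups the highest dose was combined with a modulator: melatonin, ISRIB, 4μ8C or MG132 with TG or TM, and 3-MA or MG132 with FCCP. No group received a modulator alone. Library totals ran from 26060229 counts (FCCP plus 3-MA, replicate 1) to 38717013 (TG plus 4μ8C, replicate 2). Levels are given in CPM (counts scaled by library size) as mean ± SD over the 2 libraries of a group, and changes are log2 fold changes with their standard error (SE). Adjusted p-values for genes come from edgeR and those for gene lists from camera. Of 728 counts of list members, 237 moved more than 1.5 times in at least 1 fit without a library.

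In a principal component analysis of the 500 most variable genes, the first component held 36.1% of the variance and the second 15%. The 6 MG132 libraries lay apart from all others on the first component, and the TG libraries lay apart from the TM and FCCP libraries on the second. Transcripts of the 13 protein genes of mitochondrial DNA took 1.91% (FCCP plus MG132, replicate 2) to 32.6% (TG plus ISRIB, replicate 2) of a library's counts. The other replicate of TG plus ISRIB was far lower, so that this group's mean of 19.1% had an SD of 19.1 points. TG 0.5 μM also stood out, at 15.7 ± 0.024%, beside 6.38 ± 0.485% in TG DMSO.

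**Figure D1:**
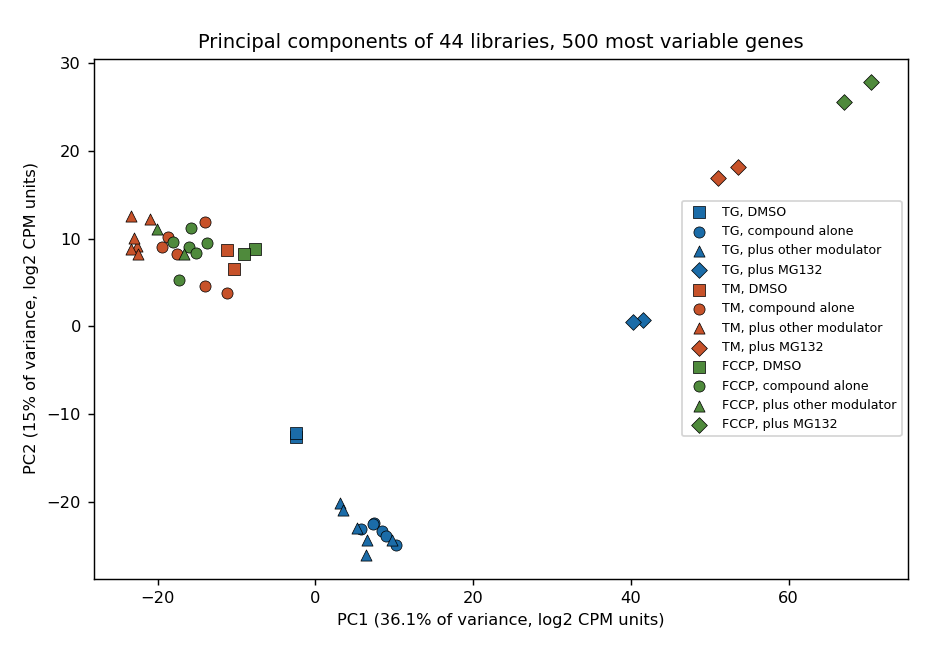
Scores of the 44 libraries on the first (36.1% of variance) and second (15%) principal components of log2 CPM for the 500 most variable genes; each point is 1 library, coloured by series and marked by treatment. The 6 MG132 libraries sit at the high end of the first component, and the TG libraries sit below the TM and FCCP libraries on the second.

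Thapsigargin blocks the pump that loads calcium into the endoplasmic reticulum (ER), and the TG series asked how the cells responded to this stress. At TG 2 μM the ER chaperones rose together: 15 of 16 were higher than in TG DMSO (median log2 change 1.43, camera adjusted p = 3.1e-10). HSPA5 (ENSG00000044574), the main chaperone of the ER lumen, rose from 870.0 ± 22.5 to 6287.2 ± 121.4 CPM (log2 change 2.85, SE 0.16, adjusted p = 6.22e-13, n = 2 in each group). DNAJB11, a partner of HSPA5, went from 70.3 to 273.5 CPM (log2 change 1.96), PDIA4, a disulfide isomerase, from 224.7 to 768.9 CPM (1.77), and MANF from 65.9 to 202.5 CPM (1.62). Genes of the integrated stress response downstream of the transcription factors ATF4 and CHOP also rose, 13 of 17 with a median log2 change of 1.35 (camera adjusted p = 4e-05). Among them were INHBE (log2 change 2.88, SE 0.25, adjusted p = 4.87e-09), PPP1R15A, which restores translation by dephosphorylating eIF2α (1.97, SE 0.18, adjusted p = 1.08e-08), ADM2 (1.97) and STC2 (1.77). DDIT3 (ENSG00000175197), which encodes CHOP, rose from 8.26 ± 2.03 to 56.6 ± 6.68 CPM (log2 change 2.78, SE 0.38, adjusted p = 1.11e-05). Of the 10 ER stress genes fixed before the data were examined, 9 rose at every TG dose; the exception was ATF3, at 47.0 ± 26.4 CPM with TG 2 μM and 15.3 ± 6.53 in DMSO (log2 change 1.62, adjusted p = 0.0822 in edgeR and 0.0243 in DESeq2). At 2 μM the call of TRIB3 was lost without any 1 of the 4 libraries (adjusted p = 0.0901 to 0.171), that of CHAC1 without TG DMSO replicate 1 (0.052) or 2 (0.0755) and that of XBP1 without TG 2 μM replicate 2 (0.108) or TG DMSO replicate 1 (0.25).

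Genes that supply amino acids to translation moved with this response. The tRNA synthetases rose in 10 of 13 cases (camera adjusted p = 4e-05), led by WARS1 (181.0 to 897.4 CPM, log2 change 2.31), CARS1 (1.44) and GARS1 (1.42). Genes of amino acid synthesis and transport rose in 14 of 18 cases (adjusted p = 6.55e-05). ASNS, which makes asparagine, went from 45.0 ± 0.633 to 265.9 ± 7.72 CPM (log2 change 2.56, SE 0.20, adjusted p = 1.4e-09) and the serine pathway genes PSAT1 (1.24) and SHMT2 (1.19) rose by less. XBP1 targets of the secretory pathway rose in 13 of 22 cases (adjusted p = 0.00182), among them DNAJB9 (1.83), SEC24D (1.07) and SERP1 (0.97). ER-associated degradation genes rose in 8 of 16 cases (adjusted p = 7.71e-05), with SEL1L at 1.45. Immediate early genes rose in 11 of 20 cases (adjusted p = 0.000562), with FOSB at 2.74, DUSP5 at 1.80 and JUN at 0.95. Cholesterol synthesis and uptake genes rose in 5 of 20 cases (adjusted p = 0.0039), and autophagy and lysosome genes in 7 of 24 cases (adjusted p = 0.00178), with NEU1 at 1.35. S phase genes fell in 8 of 20 cases and 1 rose (adjusted p = 7.22e-05). RRM2, the small subunit of ribonucleotide reductase, fell from 151.3 to 76.6 CPM (log2 change -0.98) and GINS2 fell by 0.89. In contrast CDC6, which loads the replicative helicase, rose by 0.60 (not past the threshold without TG 2 μM replicate 1 or 2 or TG DMSO replicate 1, adjusted p = 0.0534, 0.0669 and 0.122). Adjusted over the list alone, the counts were 15 ER chaperones, 14 stress response genes, 12 tRNA synthetases, 16 amino acid genes, 19 XBP1 targets, 8 degradation genes, 13 immediate early genes, 11 cholesterol genes and 10 autophagy genes higher, and 9 S phase genes lower.

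Other lists did not pass the camera test at TG 2 μM. Members past the gene threshold were 3 mitosis genes lower (adjusted p = 0.19 with an estimated correlation), 3 cell death genes higher (adjusted p = 0.0508), 5 NF-κB genes higher (adjusted p = 0.0567, with a median log2 change of 0.40 and a mean of -0.01), 3 histone genes higher (adjusted p = 0.0826) and 3 stromal marker genes lower (adjusted p = 0.0771). For the remaining lists camera gave adjusted p = 0.241 (IRE1 decay targets), 0.475 (mitochondrial chaperones and proteases), 0.401 (glycolysis and hypoxia), 0.543 (proteasome), 0.903 (heat shock), 0.944 (fatty acid synthesis), 0.19 (hepatocyte secreted proteins), 0.963 (ribosomal proteins) and 0.949 for each of NRF2 targets, metallothioneins, blood and endothelial markers, nuclear respiratory chain genes and mitochondrial DNA genes. Of these lists, IRE1 decay targets had 1 member called higher and 3 lower, and mitochondrial chaperones and proteases 2 higher and 1 lower. Glycolysis and hypoxia genes had 2 higher, and NRF2 targets and fatty acid genes each 1 higher and 1 lower. Proteasome genes and blood and endothelial markers each had 1 higher. The largest rises by the fixed rule, besides genes given above, were KLHDC7B (1.47 ± 0.0791 to 28.7 ± 1.17 CPM, log2 change 4.28, SE 0.33, adjusted p = 1.07e-09), the keratin gene KRT34 (3.95) and the NF-κB subunit gene RELB (2.89). The largest falls were METTL7A (18.6 ± 0.0778 to 3.14 ± 0.604 CPM, log2 change -2.57, SE 0.37, adjusted p = 2.19e-05), INSL4 (-2.54), AKR1C3, a steroid-reducing enzyme (-2.39), ZNF395 (-2.21), the WNT feedback gene AXIN2 (-2.13), WNT6 (-1.97), C17orf58 (-1.95) and RHOBTB1 (-1.87). In total 1325 of 14922 genes passed the threshold, 720 higher and 605 lower. Without any 1 of the 4 libraries compared the count was 610 to 676, with trends in transcript length and GC content removed it was 2242, and against TM DMSO it was 6016, with 655 of the 1325 genes called the same way and 175 the opposite way. Of the genes named here, METTL7A was higher than in TM DMSO (log2 change 1.93), and AKR1C3 (0.13) and WNT6 (0.27) were not called.

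Tunicamycin blocks N-linked glycosylation, so that proteins misfold in the ER, and the TM series asked how the cells responded. At 2 μM the ER chaperones rose more with TM than with TG, by a test of the difference between the responses (11 of 16 called, median TG minus TM difference -0.86, camera adjusted p = 0.000197). This difference was not tested at the lower doses, where HSPA5 had log2 changes of 2.95 and 3.05 with TG 0.5 and 1 μM and 2.15 and 2.18 with TM 0.5 and 1 μM. At TM 2 μM, 15 of 16 ER chaperones rose with a median log2 change of 2.77 (camera adjusted p = 1.45e-08). HSPA5 went from 1581.1 ± 38.5 to 16144.8 ± 883.6 CPM (log2 change 3.35, SE 0.16, adjusted p = 2.16e-15), CRELD2 from 32.5 to 580.3 CPM (4.16), PDIA4 from 250.0 to 2848.0 CPM (3.51) and MANF from 114.4 to 963.6 CPM (3.07). ER-associated degradation genes rose in 10 of 16 cases and fell in 1 (adjusted p = 0.000117). DERL3 (ENSG00000099958), a channel component for proteins leaving the ER, rose from 5.76 ± 0.315 to 389.6 ± 21.9 CPM (log2 change 6.08, SE 0.21, adjusted p = 2e-18), HERPUD1 rose by 3.66 and SEL1L by 2.97. XBP1 targets rose in 19 of 22 cases (adjusted p = 0.00561), with DNAJB9 at 3.94 and the vesicle coat gene SEC24D at 2.64. The ATF4 and CHOP targets rose in 15 of 17 cases (adjusted p = 0.00353), with INHBE at 3.88, ADM2 at 3.85 and SESN2 at 2.43. All 10 fixed ER stress genes rose at TM 2 μM, 8 did at each lower dose, and at the highest dose DDIT3 went from 9.81 ± 2.96 to 107.9 ± 14.1 CPM (log2 change 3.46, SE 0.39, adjusted p = 8.44e-08). Against the TG DMSO group in place of TM DMSO, 16 chaperones, 15 stress response genes and 21 XBP1 targets were higher.

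Genes of lipid and amino acid supply and of inflammation rose at TM 2 μM as well. Cholesterol genes rose in 16 of 20 cases (adjusted p = 0.0124), with STARD4 at a log2 change of 2.31 and MSMO1 at 1.71. Amino acid genes rose in 11 of 18 cases and fell in 1 (adjusted p = 0.00899), led by ALDH1L2 (3.03) and SLC3A2 (2.55), a transporter subunit. NF-κB genes rose in 12 of 19 cases (adjusted p = 0.0129), with the chemokine gene CXCL2 at 2.47 and the feedback inhibitor TNFAIP3 at 1.32. Cell death genes rose in 12 of 20 with 1 lower (adjusted p = 0.0337), where the stress cytokine gene GDF15 rose by 2.42 and the survival gene BIRC5 fell by 1.83. The tRNA synthetases rose in 9 of 13 cases (adjusted p = 0.0664 with an estimated correlation) and histone genes in 6 of 9 (adjusted p = 0.0517). Adjusted over the list alone, the counts were 16 ER chaperones, 11 degradation genes, 20 XBP1 targets, 15 stress response genes, 16 cholesterol genes, 12 amino acid genes and 12 NF-κB genes higher.

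Several lists that fell at TM 2 μM had many members that were higher in TM DMSO than in TG DMSO. Proteasome genes fell in 28 of 32 cases (median log2 change -1.01, camera adjusted p = 0.0209), among them PSMB2 (467.2 to 154.3 CPM, log2 change -1.60). Cytosolic heat shock genes fell in 14 of 18 cases and 1 rose (adjusted p = 0.0062). The co-chaperone gene FKBP4 fell by 2.30 and HSP90AB1 by 1.53, while the small heat shock protein gene CRYAB rose. Mitosis genes fell in 20 of 20 cases (adjusted p = 0.0192), with KIF20A at -1.51, CCNA2, which encodes cyclin A, at -1.42 and PLK1 at -1.18. S phase genes fell in 16 of 20 cases and CDC6 rose by 1.12 (adjusted p = 0.000232). Mitochondrial chaperones and proteases fell in 6 of 15 cases and 1 rose (adjusted p = 0.0258), with HSPE1 at -2.23 and HSPD1 at -1.58. Measured against TG DMSO instead, a comparison chosen after the values were seen, 7 proteasome genes were lower, 4 heat shock genes lower and 6 higher, and 5 mitosis genes lower and 2 higher, whereas 10 S phase genes were still lower. Of the mitochondrial chaperones and proteases 4 were then lower and 3 higher (median 0.03), with HSPE1 at -0.96 and HSPD1 at 0.32 and not called. All 4 metallothionein genes fell (adjusted p = 0.052 with an estimated correlation), 11 glycolysis and hypoxia genes fell and 1 rose (adjusted p = 0.0815), 8 NRF2 targets fell (adjusted p = 0.0814) and 13 of 36 nuclear respiratory chain genes fell (adjusted p = 0.356). Stromal markers, which HCCLM3 cells also expressed, rose in 5 of 7 cases (adjusted p = 0.0436), with the collagen gene COL5A1 at 2.04; against TG DMSO the median of the list was -0.24. Adjusted over the list alone, 30 proteasome, 14 heat shock, 20 mitosis, 17 S phase and 6 mitochondrial chaperone genes were lower and 5 stromal markers higher.

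The rule for named genes gave, as the largest rises at TM 2 μM, CCNP (0.712 ± 0.0485 to 108.2 ± 6.53 CPM, log2 change 7.24, SE 0.41, adjusted p = 5.91e-14), the cadherin gene CDH15 (7.06), KLHDC7B (6.73), LCN2, which binds iron carriers (6.66), CPAMD8 (6.45), SLC22A31 (6.36), HID1 (6.16) and DERL3. The largest falls were IL7R, the interleukin 7 receptor (11.9 ± 0.730 to 0.508 ± 0.0545 CPM, log2 change -4.54, SE 0.40, adjusted p = 6.91e-10), the WNT antagonist gene DKK1 (-3.58), IMP3 (-3.39), PLA2G4A (-3.34), the neuropeptide gene GAL (-3.34), the fatty acid binding gene FABP5 (-3.27), FOSL1 (-2.69) and GCNT3 (-2.68). In total 5534 genes passed, 2941 higher and 2593 lower. Of these, 2404 were also called the same way against TG DMSO and 388 the opposite way. With length and GC trends removed the share of calls that were higher was 41.3%, beside 53.1% without that step.

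FCCP carries protons across the inner mitochondrial membrane and so dissipates the gradient that drives ATP synthesis, and the FCCP series asked what this stress did over a range of doses. At FCCP 5 μM the ER chaperones were lower, not higher: 10 of 16 fell (median log2 change -0.53, camera adjusted p = 7e-04), among them CALR, a lectin chaperone (1461.8 to 698.4 CPM, log2 change -1.07), PPIB (-1.11) and MANF (-0.79). All 32 proteasome genes fell (median -1.04, adjusted p = 0.022), with PSMA4 at -1.56. Heat shock genes fell in 12 of 18 cases and 1 rose (adjusted p = 0.0354), with HSP90AA1 at -1.73 and CHORDC1 at -1.65. Mitochondrial chaperones and proteases fell in 7 of 15 cases (adjusted p = 0.015), with HSPE1 at -1.70 and GRPEL1 at -1.01; HSPD1, the mitochondrial chaperonin, went from 771.3 ± 12.2 to 289.3 ± 13.8 CPM (log2 change -1.41, SE 0.22, adjusted p = 3.39e-05). Against TG DMSO in place of FCCP DMSO, 3 ER chaperones and 1 proteasome gene were lower, and 8 heat shock genes were higher. HSPD1 (0.27), HSP90AA1 (0.47) and MANF (0.10) were then not called, and CHORDC1 was higher (1.00).

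Calls of stress markers with FCCP depended on the DMSO group used as reference. Against FCCP DMSO, of the 14 genes fixed for FCCP, 1 rose and 3 fell at 5 μM: ASNS rose from 84.8 ± 21.4 to 137.3 ± 12.3 CPM (log2 change 0.70, SE 0.19, adjusted p = 0.00823), and HSPD1, DDIT3 (-1.12) and HSPA5 (-0.55) fell. The call of ASNS was lost without FCCP 5 μM replicate 1 (adjusted p = 0.0785) or FCCP DMSO replicate 2 (0.137), that of HSPA5 without the same libraries (0.0576 and 0.099), and that of DDIT3 without FCCP 5 μM replicate 1 (0.0785) or 2 (0.148) or FCCP DMSO replicate 1 (0.183). At 1.25 μM 5 of the 14 fell and at 2.5 μM 4 did. ATF4 was at 389.0 ± 71.9 CPM in DMSO and 375.6 ± 22.4 at 5 μM (adjusted p = 0.871), GDF15 at 47.9 ± 3.97 and 45.0 ± 1.00 (adjusted p = 0.765) and FGF21 at 0.0751 ± 0.0260 and 0.243 ± 0.0321 (adjusted p = 0.166). Against TG DMSO instead, a reference chosen after the values were seen, ASNS (log2 change 1.61), SQSTM1 (1.40), ATF5 (0.80) and ATF4 (0.58) were called higher, and HSPD1 (0.27), DDIT3 (-0.25) and HSPA5 (-0.02) were not called. That group belongs to another series, so an effect of FCCP cannot be told apart from a difference between series. SQSTM1 was at 855.8 ± 108.5 CPM in FCCP DMSO, 672.5 ± 81.9 at FCCP 5 μM and 255.5 ± 15.6 in TG DMSO. The ATF4 and CHOP targets rose in 6 of 17 cases and fell in 1 (adjusted p = 0.386 with an estimated correlation), with ADM2 at 1.52 and DDIT3 the member that fell. Nuclear respiratory chain genes fell in 17 of 36 cases (adjusted p = 0.386), with SDHB, a subunit of complex II, at -1.50 and UQCRB at -0.95 (-0.45 and 0.08 against TG DMSO, neither called), and 5 of 36 ribosomal protein genes fell (adjusted p = 0.542). Glycolysis and hypoxia genes fell in 8 of 21 cases and rose in 2 (adjusted p = 0.517). All 4 metallothionein genes fell (adjusted p = 0.0817), with MT1X at -2.26, and 10 of 20 mitosis genes fell (adjusted p = 0.246). Adjusted over the list alone, 10 ER chaperones, 32 proteasome, 12 heat shock, 7 mitochondrial chaperone and 23 nuclear respiratory chain genes were lower.

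Of the largest rises with FCCP 5 μM, 2 were in collagen genes. These were COL4A4 (log2 change 2.59) and COL5A1 (69.6 ± 19.4 to 385.2 ± 28.5 CPM, 2.47, SE 0.18, adjusted p = 3.22e-10). H6PD, an NADPH source of the ER lumen, rose more (7.95 ± 0.180 to 58.5 ± 0.0141 CPM, 2.88, SE 0.19, adjusted p = 4.89e-11). Stromal markers as a list rose in 5 of 7 cases (adjusted p = 0.0354), and against TG DMSO the median of the list was -0.43. The transcription factor gene SALL4 (2.47), ZNF736 (2.26), FRY (2.24) and NPIPB5 (2.25, a gene with near-identical copies, so its counts are uncertain) were also among the rises. The largest falls were GAL (-2.59), FABP5 (-2.26), MT1X, CD68 (-2.17), the protein C receptor gene PROCR (-2.14), GCNT3 (-2.08), RPS19BP1 (-1.99) and MPDU1 (-1.96). Of these genes, RPS19BP1 was not called without FCCP DMSO replicate 1 (adjusted p = 0.214), ZNF736 without FCCP DMSO replicate 1 (0.0622) or 2 (0.0542), NPIPB5 without FCCP 5 μM replicate 2 (0.0816), and GCNT3 without FCCP 5 μM replicate 1 (0.177) or FCCP DMSO replicate 1 (0.0598) or 2 (0.0582). In total 4097 genes passed, 1987 higher and 2110 lower. The count was 1963 to 2491 without FCCP DMSO replicate 1 or either FCCP 5 μM replicate, and 2039 against TG DMSO, with 420 of the 4097 genes called the same way and 292 the opposite way. Against TG DMSO the log2 changes of SALL4 (-0.12), ZNF736 (-0.04), FABP5 (0.08), RPS19BP1 (0.23) and MPDU1 (0.26) had the other sign and none of the 5 was called. Calls lost against TG DMSO with the sign kept are not listed here. COL5A1 was at 332.4 ± 19.5 CPM with TG 2 μM, where no stromal marker was called higher than in TG DMSO. Its rise with FCCP thus also depends on the low level in FCCP DMSO.

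The DMSO groups of the series were compared because all were nominal dose 0. TG DMSO differed from both others in many stress genes: HSPA8, the constitutive heat shock chaperone, was at 340.0 ± 9.87 CPM in TG DMSO, 2218.0 ± 519.6 in TM DMSO (log2 difference -2.71, SE 0.25, adjusted p = 2.14e-09) and 3041.5 ± 100.7 in FCCP DMSO (-3.16). Heat shock genes were lower in TG DMSO than in TM DMSO in 13 of 18 cases (camera adjusted p = 0.0263). ER chaperones were lower in 10 and higher in 1 of 16 (adjusted p = 0.0263), proteasome genes lower in 21 of 32 (adjusted p = 0.132 with an estimated correlation) and mitosis genes lower in 16 of 20 (adjusted p = 0.132). Stromal markers were higher in 6 of 7 cases and lower in 1 (adjusted p = 0.0445), with COL1A1 at 106.4 CPM in TG DMSO and 18.4 in TM DMSO (log2 difference 2.53). Against FCCP DMSO the counts were 15 heat shock genes (adjusted p = 0.0199), 8 ER chaperones (adjusted p = 0.029), 27 proteasome genes (adjusted p = 0.0681) and 13 mitosis genes lower (adjusted p = 0.145). Named by the rule were METTL7A (0.818 ± 0.0740 in TM DMSO, 18.6 ± 0.0778 in TG DMSO, log2 difference 4.50) and the tight junction gene TJP3 (4.30) among those higher in TG DMSO, and UTP20 (-2.94) and ALMS1 (-2.75) among those lower. Across all genes, 6263 differed between TG and TM DMSO (3198 higher in TG DMSO) and 6245 between TG and FCCP DMSO (3018 higher). Between TM and FCCP DMSO edgeR called 3 genes, with 2718 at an unadjusted p under 0.05 and 537 called by DESeq2; the count was 1636 without FCCP DMSO replicate 2, 0 without FCCP DMSO replicate 1 or TM DMSO replicate 2, and 6 without TM DMSO replicate 1. The TG to FCCP count was 4114 without FCCP DMSO replicate 1.

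The dose range was tested directly as highest against lowest dose. With TM, 1966 genes differed between 2 and 0.5 μM, 1033 higher and 933 lower. In pairs compared after the data were seen, the difference lay with the 2 μM libraries: 1366 genes differed between 2 and 1 μM, and edgeR called 0 between 1 and 0.5 μM (1112 at an unadjusted p under 0.05; DESeq2 was not run on this pair). HSPA5 averaged 7011.5 CPM at 0.5 μM, 7151.6 at 1 μM and 16144.8 at 2 μM. TG gave 6 genes between 2 and 0.5 μM, 3 in each direction, and FCCP 41 between 5 and 1.25 μM, 37 higher and 4 lower. For these TG and FCCP ranges DESeq2 called 108 and 135 genes, of which 17.6% and 61.5% were higher. Calls against DMSO numbered 3033 at TG 0.5 μM, 1824 at 1 μM and 1325 at 2 μM; 1115 of the genes called at 0.5 μM were called the same way at 2 μM (covariance 0.595, beside 0.172 in simulated unchanged groups that share a DMSO group). HSPA5 was at 6743.0 ± 2.75 CPM at TG 0.5 μM, beside 6287.2 ± 121.4 at 2 μM. TM called 4174, 4822 and 5534 genes at rising doses, with 3041 shared in direction and 30 opposite between the lowest and the highest, and FCCP called 3709, 3144 and 4097, with 2632 shared. Left-out libraries moved these counts: without any 1 of their 4 libraries, TG 0.5 μM gave 1412 to 1658 genes, TG 1 μM 930 to 1107, the TG range 0 to 11, the TM range 685 to 1243 and the FCCP range 3 to 6. TM 0.5 μM gave 2528 without TM DMSO replicate 2 and TM 1 μM 3173 without its own replicate 2 and 3192 without that DMSO library. FCCP 1.25 μM gave 1410 to 2349 and FCCP 2.5 μM 1318 to 1844 without FCCP DMSO replicate 1 or either library of the dose.

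TG, TM and FCCP were compared at their highest doses as a difference of responses, each against its own DMSO group. DERL3 gave the largest difference in favour of TM among genes named here: it rose by 0.66 with TG and by 6.08 with TM (difference -5.42, SE 0.26, adjusted p = 1.18e-14). CDH15 (1.82 with TG, 7.06 with TM), CPAMD8 (1.34 and 6.45) and PRODH, which degrades proline (-1.46 and 3.73), followed. In the opposite direction FOSL1, a subunit of the AP-1 factor, rose by 1.95 with TG and fell by 2.69 with TM (difference 4.64, SE 0.54, adjusted p = 7.18e-07), and FABP5 had log2 changes of 0.33 (adjusted p = 0.548) and -3.27. DDIT3 rose by 2.78 with TG and fell by 1.12 with FCCP (difference 3.89, SE 0.53, adjusted p = 7.85e-06), while KIF26B (-1.70 and 2.17), ZNF395 (-2.21 and 1.47) and COL4A4 (-0.72 and 2.59) went the other way. CCNP differed between TM and FCCP by 6.57 (SE 0.56, adjusted p = 1.37e-09), and DGAT2, which makes triglycerides, by -2.90. The tests of the difference called 3477 genes for TG against TM, 3318 for TG against FCCP and 1386 for TM against FCCP. TM 2 μM and FCCP 5 μM shared 2416 genes called the same way against their DMSO groups and 122 the opposite way, where independent lists would share 758.3 in the same direction; TG and TM shared 592 in direction (247 if independent) and had 190 opposite (244.4). TG and FCCP shared 194 (181.4) and had more, 342, opposite (182.4). The TM to FCCP count was 788 to 899 without FCCP 5 μM replicate 2, FCCP DMSO replicate 1, TM DMSO replicate 1 or either TM 2 μM replicate. The 2 counts that involve TG rest on a TG DMSO group that differed from the other DMSO groups.

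Modulators were added to TG 2 μM to ask what each changed in the response. With melatonin, edgeR called 0 genes, with 347 at an unadjusted p under 0.05 and 1 called by DESeq2; 1 gene was called without TG 2 μM replicate 1. The 347 is fewer than a threshold of 0.05 would pass among 14922 unchanged genes, so it gives no sign of further changed genes. Lists shifted by small amounts in camera: S phase genes had a median log2 change of -0.21 (adjusted p = 5.49e-05), ER chaperones 0.15 (adjusted p = 0.00163), degradation genes 0.15 (adjusted p = 0.00163), histones 0.33 (adjusted p = 0.0172) and cell death genes 0.08 (adjusted p = 0.0484). With simulated changes in these groups edgeR recovered 47.8% of genes changed 2-fold and 77.3% of those changed 4-fold, so changes of that size in single genes were detectable in part.

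ISRIB relieves the translation block of the integrated stress response. STC2 was the 1 of 17 members of the ATF4 and CHOP list that was called, and it fell (144.7 ± 4.72 to 77.5 ± 12.3 CPM, log2 change -0.90, SE 0.16, adjusted p = 0.00345; list adjusted p = 0.337 with an estimated correlation). ER chaperones rose further in 8 of 16 cases (median log2 change 0.68, adjusted p = 2.14e-08), with MANF at 1.31, HSP90B1 at 1.39 and PDIA4 at 1.16, and degradation genes in 5 of 16 (adjusted p = 4.23e-05), with DERL3 at 1.98. Cholesterol genes rose in 6 of 20 cases (adjusted p = 0.000177), with LSS at 0.94, and fatty acid genes in 2 of 13 (adjusted p = 0.00902), ACSS2 (1.28) and SCD (0.78). UHRF1 (-0.93) was the S phase gene that fell (adjusted p = 4.23e-05 for the list). Mitochondrial DNA genes rose in 10 of 13 cases (adjusted p = 0.127), with MT-ND6 at 617.1 ± 88.2 and 3808.7 ± 4389.2 CPM (log2 change 2.63, SE 0.57, adjusted p = 0.0207), and blood and endothelial markers in 2 of 7 (adjusted p = 0.127), the haemoglobin genes HBA1 and HBB. Both were low at TG 2 μM alone, HBA1 at 1.69 ± 0.224 CPM and HBB at 0.0804 ± 0.114 CPM. Mitochondrial transcripts took 5.52% of TG plus ISRIB replicate 1, beside a mean of 6.11% at TG 2 μM, so their higher share came from replicate 2. The list tests in camera pooled the spread over all groups and were not repeated without a library. Their p-values may thus be too small for this group, whose replicates were unlike. By the rule the rises also held SERPING1 (2.32), IL21R (2.27) and LAMP3 (2.12), and the falls RASSF1 (-0.89) and PIGW (-0.89). Without TG plus ISRIB replicate 2 the log2 changes were 0.19 for MT-ND6, 0.59 for LAMP3, 0.77 for SERPING1, -0.75 for STC2, -0.71 for UHRF1, -0.76 for RASSF1, -0.52 for PIGW and 0.76 for SCD, and these genes were no longer called. HBA1 and HBB were not called without replicate 1 (adjusted p = 0.178 and 0.0982). Without TG 2 μM replicate 1 the calls of all of these except ACSS2, MANF, HSP90B1, PDIA4 and DERL3 were lost, STC2 at 0.0611 and LSS at 0.0718 among them, and without its replicate 2 those of IL21R (0.137), SCD (0.109) and UHRF1 (0.109) were among the lost calls. In total 176 genes passed, 152 higher and 24 lower, and the count moved with single libraries: it was 2369 without TG plus ISRIB replicate 1, 48 without replicate 2 (the library with 32.6% mitochondrial transcripts), 10 without TG 2 μM replicate 1 and 36 without its replicate 2. DESeq2 called 417, and removing length and GC trends gave 638, of which 53.3% were higher. Against TG 1 and 0.5 μM in place of TG 2 μM, compared after the data were seen, TG plus ISRIB differed in 26 and 50 genes.

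4μ8C inhibits IRE1, the ER sensor that splices XBP1 mRNA. With it, 3 of 22 XBP1 targets were lower than with TG alone (camera adjusted p = 0.00792): SSR3 (154.3 ± 0.0780 to 67.5 ± 0.217 CPM, log2 change -1.19, SE 0.17, adjusted p = 0.0012), SEC24D (-0.92) and DNAJB9 (-1.13). INHBE fell by 1.41 and the matrix enzyme gene LOX by 1.04, while EGR1 (2.13), ZNF395 (1.70), ACTA2 (1.54) and TMEM8B (1.42) rose. Among ER chaperones PPIB fell by 0.89 and MANF rose by 0.67 (median of the list -0.47, adjusted p = 0.00348), and 1 cholesterol gene, LSS, fell (list adjusted p = 0.00348). Camera also passed glycolysis and hypoxia genes (adjusted p = 0.031, median -0.33), cell death genes (adjusted p = 0.031, 1 of 20 higher), immediate early genes (adjusted p = 0.0438, 2 of 20 higher) and fatty acid genes (adjusted p = 0.0471). Adjusted over the list alone, 10 XBP1 targets and 8 ER chaperones were lower. Against TG 1 and 0.5 μM in place of TG 2 μM, compared after the data were seen, TG plus 4μ8C differed in 235 and 275 genes. Of the genes named here, SSR3 kept its call without any 1 of the 4 libraries. The others lost theirs without at least 1 of them: without TG 2 μM replicate 1 adjusted p was 0.298 for DNAJB9, 0.0691 for SEC24D, 0.155 for PPIB, 0.4 for MANF, 0.183 for LSS, 0.299 for LOX, 0.402 for EGR1, 0.288 for TMEM8B, 0.183 for ACTA2 and 0.0806 for ZNF395. Without TG plus 4μ8C replicate 1 it was 0.0837 for INHBE. Without TG 2 μM replicate 2 it was 0.239 for DNAJB9, 0.0564 for SEC24D and 0.307 for PPIB, and without TG plus 4μ8C replicate 2 it was 0.195 for DNAJB9, 0.0605 for SEC24D and 0.143 for LOX. In total 50 genes passed, 19 higher and 31 lower; 28 of them went opposite to the TG response and 7 the same way. The comparisons share the TG 2 μM libraries, and their covariance was -0.229, beside -0.18 in simulated unchanged groups. DESeq2 called 170 genes and the fit with length and GC trends removed 178, and the count was 9 without TG 2 μM replicate 1, 16 without its replicate 2, 25 without TG plus 4μ8C replicate 1 and 82 without its replicate 2.

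ER stress genes were lower with melatonin, ISRIB or 4μ8C added to TM 2 μM than with TM 2 μM alone. HSPA5 went from 16144.8 ± 883.6 CPM with TM alone to 4717.9 with melatonin (log2 change -1.77, SE 0.15, adjusted p = 2.75e-09). ER chaperones fell in 14, 14 and 15 of 16 cases with melatonin, ISRIB and 4μ8C (medians -1.23, -1.20 and -1.53; camera adjusted p = 7.51e-08, 1.83e-07 and 6.3e-09), and XBP1 targets in 20, 20 and 22 of 22 cases (adjusted p = 7.84e-05, 0.000117 and 1.89e-05). SEC24D went from 181.5 ± 6.76 to 24.8 ± 2.40 CPM with ISRIB (-2.87, SE 0.17, adjusted p = 5.24e-12) and to 13.4 ± 1.02 with 4μ8C (-3.76, SE 0.18, adjusted p = 1.23e-14). ATF4 and CHOP targets fell in 13, 12 and 11 of 17 cases (adjusted p = 0.00152, 0.00566 and 0.0296); INHBE fell by 3.09 with melatonin. Degradation genes fell in 11, 11 and 13 of 16 (adjusted p = 7.75e-06, 1.27e-05 and 5.36e-07; 1 rose with melatonin and 1 with ISRIB). Cholesterol genes fell in 11, 9 and 15 of 20 (adjusted p = 0.00461, 0.0064 and 0.000411) and NF-κB genes in 8, 7 and 10 of 19 (adjusted p = 0.0011, 0.0064 and 0.00204). S phase genes rose in 9, 9 and 8 of 20 cases (adjusted p = 0.000801, 0.000401 and 0.03), among them UHRF1 with melatonin (1.30), and CDC6 fell in all 3 (-1.22, -1.17 and -1.57). Adjusted over the list alone, 14, 14 and 16 ER chaperones and 21, 21 and 22 XBP1 targets were lower.

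The same genes led the lists of all 3 combinations. HID1 fell by 3.84 with melatonin, 3.75 with ISRIB and 4.85 with 4μ8C, and CCNP by 3.63, 3.53 and 4.81, while IMP3 rose by 2.76, 3.00 and 2.93, the adhesion gene BCAM by 2.70, 2.63 and 3.22 and DGAT2 by 2.40, 2.38 and 3.24. Melatonin called 2060 genes (1000 higher, 1060 lower), ISRIB 2152 (1054 and 1098) and 4μ8C 2516 (1198 and 1318). Of these, 1704 were called the same way by melatonin and ISRIB and 0 the opposite way in edgeR, 1465 the same way and 7 the opposite way by melatonin and 4μ8C, and 1458 and 12 by ISRIB and 4μ8C (same way if independent: 148.6, 173.9 and 181.6). The 3 pairs share the TM 2 μM libraries, so part of the agreement may come from these: their covariance was 0.573, 0.56 and 0.539, beside 0.183, 0.186 and 0.181 in simulated unchanged groups. Direct comparison of the combinations called 2 genes between ISRIB and melatonin, 197 between 4μ8C and melatonin and 370 between 4μ8C and ISRIB. Between ISRIB and melatonin 269 genes had an unadjusted p under 0.05, fewer than unchanged genes would give. Calls opposite to the TM response numbered 1073, 1064 and 1156, and calls in its direction 206, 217 and 319. These comparisons share the same libraries, and their covariance was -0.437, -0.464 and -0.398, beside -0.186, -0.183 and -0.183 in simulated unchanged groups. Against TM 1 μM in place of TM 2 μM, chosen after the values were seen, the combinations gave 210, 187 and 878 genes, of which 59, 46 and 242 were opposite to the TM response, and IMP3 had log2 changes of -0.24, 0.00 and -0.07. Against TM 0.5 μM the combinations gave more, 865, 952 and 1584 genes. Without any 1 of the 4 libraries the melatonin count was 966 to 1179 and the 4μ8C count 1300 to 1666, and the ISRIB count was 993 to 1274 without TM plus ISRIB replicate 2 or either TM 2 μM replicate.

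**Figure D2:**
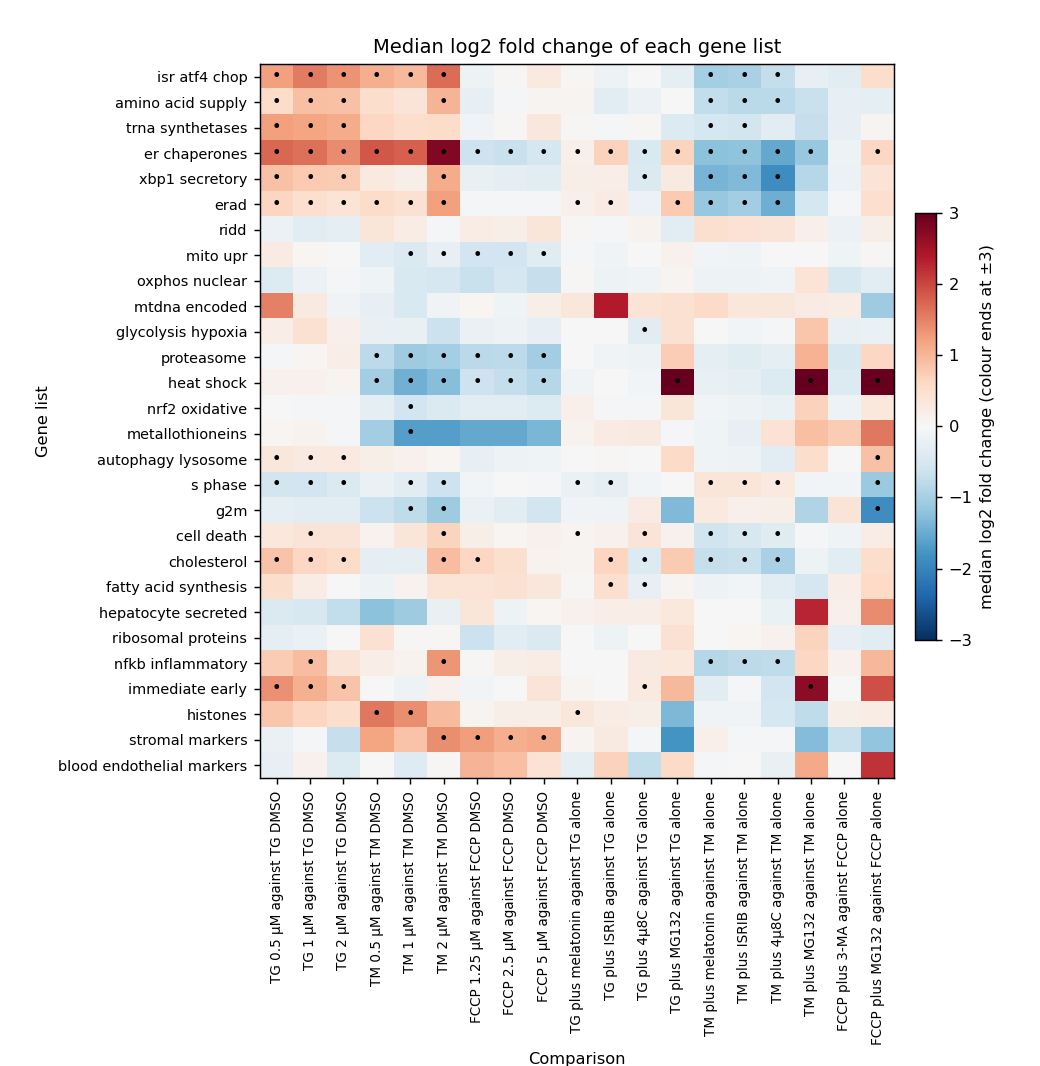
Median log2 change of 28 gene lists (vertical) in 19 comparisons (horizontal), by colour with the scale ending at -3 and 3; a dot marks a camera adjusted p under 0.05 with an estimated correlation. ER chaperones had medians of 1.43 with TG 2 μM, 2.77 with TM 2 μM and -0.53 with FCCP 5 μM, and heat shock genes had medians of 4.09, 4.08 and 4.58 when MG132 was added.

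MG132 blocks the proteasome, and adding it changed more genes than any other modulator in each series. All 18 cytosolic heat shock genes rose with TG, TM and FCCP alike (medians 4.09, 4.08 and 4.58; camera adjusted p = 3.59e-05, 5.78e-05 and 0.000144). DNAJB1, a partner of HSP70, rose from 105.9 to 4485.3 CPM with TG and HSPH1 from 68.8 to 2813.6 CPM with FCCP (5.35). HSPA6 rose from 0.501 ± 0.103 to 1031.3 ± 321.9 CPM with TG (SE of the log2 change 1.35, adjusted p = 5.92e-07) and by 11.70 on the log2 scale with TM. HSPA1A went from 301.6 ± 28.6 to 31011.7 ± 865.1 CPM with TG (6.68) and HSPA1B from 286.5 ± 23.0 to 26748.5 ± 985.3 (6.54); as near-identical genes, their split of the counts is uncertain. Proteasome genes rose in 19, 28 and 17 of 32 cases (adjusted p = 0.194, 0.0923 and 0.475 with an estimated correlation; 2 fell with FCCP), with PSMC4 at 1.67, 1.53 and 1.47. Mitosis genes fell in 16, 15 and 19 of 20 cases (adjusted p = 0.107, 0.123 and 0.0171), with TOP2A, a DNA topoisomerase, at -2.89, -3.21 and -3.11.

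When MG132 was added, ER chaperones rose in 11 of 16 cases and fell in 1 with TG (adjusted p = 0.00485), where HSPA5 reached 46322.8 CPM (log2 change 2.88, SE 0.16, adjusted p = 4.94e-14). They rose in 9 and fell in 1 with FCCP (adjusted p = 0.0171), where HSPA5 went from 857.0 to 9442.0 CPM (3.46). With TM they fell in 13 cases (adjusted p = 0.000156), with HSP90B1 at -2.71 and CRELD2 at -1.88, and the 1 that rose was HSPA5 (16144.8 to 23222.4 CPM, log2 change 0.52), which was thus higher with MG132 in all 3 series. Degradation genes rose in 12 cases and fell in 1 with TG (adjusted p = 0.00485). Immediate early genes rose in 18 of 20 cases with TM (adjusted p = 0.00135), with DUSP1 at 3.55 and JUN at 3.39, and in 13 with 1 lower with FCCP (adjusted p = 0.0626). Autophagy genes rose in 16 of 24 cases and fell in 1 with FCCP (adjusted p = 0.00835), and S phase genes fell in 17 of 20 and rose in 1 (adjusted p = 0.000144), with GINS2 at -2.54 and TYMS at -2.31. Immunoglobulin heavy chain genes, near-identical copies whose counts are uncertain, appeared: IGHG4 was at least 862-fold higher with TM and at least 3600-fold with FCCP, and IGHG1 at least 256-fold and at least 1650-fold, against groups with no counts and a floor of 3 counts over the group. SYNPO2L (at least 2460-fold) and KRT6A (at least 1270-fold) appeared with FCCP. DESeq2 did not call IGHG4 (adjusted p = 0.332 with TM and 0.235 with FCCP) or KRT6A (0.301). INHBE fell by 4.12 with TG and by 4.21 with TM, C5 by 4.37 with TM and LRRC26 by 5.74 with FCCP. MG132 called 6902 genes with TG (3223 higher), 7570 with TM (3613 higher) and 7915 with FCCP (4118 higher), of which TG and TM shared 4689 in direction (1756 if independent), TM and FCCP 4312 (2004) and TG and FCCP 3950 (1825.6).

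3-MA is used as an inhibitor of autophagy, commonly at mM concentrations. The labels gave 5 μM, so whether autophagy was inhibited is not known from these data. TAGLN, a marker of smooth muscle, fell from 96.9 ± 21.1 to 15.0 ± 1.04 CPM (log2 change -2.69, SE 0.24, adjusted p = 5.81e-08), and PSG5 (-2.35), BLCAP (-2.00) and TMEM19 (-1.86) followed. DHRS2, a reductase, rose from 8.73 ± 0.275 to 38.4 ± 9.08 CPM (2.14, SE 0.24, adjusted p = 2.29e-06), and the histone genes H2AC8 (1.47), H3C15 (1.67) and H3C14 (1.65) rose, the last pair being near-identical and so uncertain in split. TMEM19 was not called without any 1 of the 4 libraries (adjusted p = 0.0966 to 0.256) or without the filter on low counts (0.0674), and H2AC8 not without FCCP plus 3-MA replicate 2 (0.0545). No list passed camera; the lowest adjusted p was 0.1 for heat shock genes (3 of 18 fell), and of the autophagy genes 1 of 24 fell (adjusted p = 0.842). In total 456 genes passed, 200 higher and 256 lower, with 123 opposite to the FCCP response and 85 in its direction. The comparisons share the FCCP 5 μM libraries, and their covariance was -0.272, beside -0.167 in simulated unchanged groups. DESeq2 called 783 and the fit with length and GC trends removed 1112, and the count was 131 to 153 without FCCP plus 3-MA replicate 2 or either FCCP 5 μM replicate.

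Whether a modulator acted differently with TG than with TM was tested as a difference of effects. HID1, high with TM alone, fell with melatonin by 3.84 in TM and had a log2 change of 0.56 in TG (difference 4.40, SE 0.40, adjusted p = 4.17e-08). With ISRIB it fell by 3.75 in TM and rose by 1.44 in TG (5.19, SE 0.41, adjusted p = 8.17e-10), and IL21R went the same ways (-3.22 and 2.27). With 4μ8C it fell in both, by 4.85 in TM and 1.80 in TG (3.06, SE 0.41, adjusted p = 1.9e-05). DERL3 fell by 3.52 with MG132 in TM and rose by 0.48 in TG (4.00, SE 0.25, adjusted p = 6.45e-12), and SOX9, a transcription factor gene, rose by 5.18 in TM with a log2 change of 0.03 in TG. IGFBP1, a hepatic growth factor binding protein, fell by 3.54 with MG132 in TG and rose by 5.08 in FCCP (difference -8.63, SE 0.51, adjusted p = 1.74e-12), and ID1 rose by 2.17 in TM and fell by 1.69 in FCCP. The tests called 1028 genes for melatonin, 1495 for ISRIB, 1068 for 4μ8C and 1817 for MG132 between TG and TM, and for MG132 4468 between TG and FCCP and 4235 between TM and FCCP. The TM side of these tests used the TM 2 μM libraries, which differed from TM 1 μM in 1366 genes. Another TM dose was not tested in its place, so a trait of the TM 2 μM libraries cannot be told apart from a modulator effect. The melatonin count was 555 to 672 without TG 2 μM replicate 2, TM 2 μM replicate 2 or any 1 of the 4 melatonin libraries. The 4μ8C count was 577 to 669 without replicate 1 of either combination or any 1 of the 4 libraries of TG or TM 2 μM alone. The ISRIB count was 2996 without TG plus ISRIB replicate 1 and 905 to 985 without TM 2 μM replicate 2, TM plus ISRIB replicate 2 or either TG 2 μM replicate. The MG132 count between TG and TM was 1130 without TM plus MG132 replicate 1 and 1148 without TM 2 μM replicate 2.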

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

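Tests and alternatives chosen only after the results were seen were those that removed length and GC trends or mitochondrial DNA genes, exchanged DMSO or TM reference groups, followed FCCP or TM doses, or compared with TG plus melatonin; the 2 on replicates of TG plus ISRIB were set before their results.

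Responses to TG, TM and FCCP differed by an interaction test in 3477 genes for TG against TM, 3318 for TG against FCCP and 1386 for TM against FCCP. Effects of a modulator differed by the same test between TG and TM in 1028 genes for melatonin, 1495 for ISRIB, 1068 for 4μ8C and 1817 for MG132. For MG132 they also differed between TG and FCCP in 4468 genes and between TM and FCCP in 4235. The TM side of all these tests used the TM 2 μM libraries, which differed from TM 1 μM in 1366 genes. All 9 counts compare series. Without drugs, TG DMSO differed from TM DMSO in 6263 genes and from FCCP DMSO in 6245. TM and FCCP DMSO differed in 3 genes in edgeR and 537 in DESeq2. What made the DMSO groups differ, and whether it altered how the cells responded to the drugs, was not tested. Exchanged references did change the calls. Of 4097 genes called with FCCP 5 μM, 420 were called the same way against TG DMSO and 292 the opposite way.

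TM 2 μM and FCCP 5 μM moved 2416 genes the same way against their DMSO groups, although the compounds act on different organelles. Length and GC trends are argued against as the whole cause, since 1994 of these genes were called the same way in both once they were removed. A candidate explanation is that TM and FCCP DMSO libraries shared a state that TG DMSO and the drugged libraries lacked: genes called with TM differed in the matching direction between TG and FCCP DMSO by a median of 0.52 log2 (quartiles 0.03 and 1.05). A response common to both drugs stays open, because these genes moved further from the lowest to the highest FCCP dose by a median of 0.09, as a response already full at the lowest dose also would.

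Melatonin, ISRIB and 4μ8C, which act on different targets, changed the TM 2 μM profile alike. Length and GC trends are argued against as the whole cause, since 5860 of the 6728 calls of the 3 combinations were also made the same way with them removed. A candidate explanation is that the TM 2 μM libraries stood apart from the other TM libraries, since against TM 1 μM the combinations had 19% of those calls (1275). Against TM 0.5 μM, however, melatonin, ISRIB and 4μ8C gave 865, 952 and 1584 genes, so this low share rests on the TM 1 μM reference. That each modulator lowered the response to TM cannot be told apart from a lower effective dose: TM 2 μM differed from TM 1 μM alone in 1366 genes, and no group received a modulator alone.

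TG plus ISRIB differed from TG alone in 176 genes, and its replicate 2 held 32.6% mitochondrial transcripts. Length and GC trends are argued against as the whole cause, since 172 of the calls were also made the same way with them removed. The share of mitochondrial transcripts stays open: 158 calls were also made without those genes, but their removal shifted the median log2 change by 0.002 and so decides nothing. Of the genes called with replicate 2 alone, 31% had the same sign in replicate 1 against TG 1 μM. An ISRIB effect shared by the replicates would give agreement, but most signs were opposite, so another difference between these libraries took part. Length and GC trends held 15.8% of the variance of deviations in replicate 1 and 1.5% in replicate 2. The comparison was not repeated without these trends and does not decide on an ISRIB effect. For the genes called with both replicates an ISRIB effect stays open, with 33.5% also called the same way against TG plus melatonin. Whether replicate 2 by itself made those calls is open too: the median ratio of the log2 change without it to that with it was 0.78, with quartiles of 0.47 and 1.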

How the results depend on the processing

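The removal of length and GC trends, the removal of mitochondrial DNA genes and the exchanged DMSO and TM reference groups were chosen after the data were seen; the other alternatives were planned. Of 417 named results for single genes, 274 kept their side of the threshold, and their sign where called in either fit, under every alternative run on them. With left-out libraries set aside, 301 did so. Not all alternatives apply to each: the fit within a series covers 327, and the exchanged references 142 (TG DMSO), 64 (TM DMSO) and 54 (TM 1 μM). Sign changes were counted only for results called in the main fit or in the alternative. Such changes occurred only with exchanged references, in 22, 3 and 2 of these results. Single-gene calls changed in 7 cases with DESeq2 (3 lost, 4 gained), 0 with RLE size factors, 6 without the filter on low counts (all lost), 9 with a block for replicate (all lost), 24 of 327 with only the libraries of the same series (22 lost, 2 gained), 3 with length and GC trends removed (1 lost, 2 gained), 0 of 416 without mitochondrial DNA genes and 69 when 1 library was left out (all lost). Of 616 list tests in camera, 1 was lost and 6 gained with the block, 1 lost and 6 gained with RLE, and 154 gained with the preset correlation. Of 728 counts of list members, those that moved more than 1.5 times numbered 65 with DESeq2, 11 with RLE, 30 without the filter, 29 with the block, 80 within the series, 145 with length and GC trends removed, 3 without mitochondrial DNA genes, 237 in at least 1 of the 4 fits with 1 library left out (551 of 2912 values), 55 of 112 with TG DMSO, 32 of 56 with TM DMSO and 103 of 224 with TM 1 μM as reference.

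Counts of called genes that moved more than 1.5 times are given with their value, and the cause was not tested except where stated. The removal of mitochondrial DNA genes moved none of the 34 counts. With DESeq2 the counts were 108 for TG 2 against 0.5 μM, 135 for FCCP 5 against 1.25 μM, 1 for TG plus melatonin, 417 for TG plus ISRIB, 170 for TG plus 4μ8C, 783 for FCCP plus 3-MA and 537 for TM against FCCP DMSO. Calls opposite to the drug response were 1, 58 and 54 for melatonin, ISRIB and 4μ8C with TG, and 192 for 3-MA with FCCP. RLE size factors gave 2 genes for the TG range, and no filter gave 9 for the FCCP range and 14 calls opposite to TG for ISRIB. The replicate block gave 0 for the TG range in edgeR (main value 6, 1895 at an unadjusted p under 0.05 and 108 in DESeq2, both without the block) and 10 for the FCCP range. Replicate numbers showed no common pairing of libraries, so this block was an alternative only. With only the libraries of the same series, a fit with fewer residual degrees of freedom, the counts were 1 for the TG range, 0 for the FCCP range (1751 at an unadjusted p under 0.05 and 135 in DESeq2 over all libraries), 2 for TG plus melatonin, 21 for TG plus ISRIB, 10 for TG plus 4μ8C and 166 for FCCP plus 3-MA, with 2, 3, 8 and 57 calls opposite to the response.

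Removing length and GC trends gave 2849 for TG 1 μM, 2242 for TG 2 μM, 26 and 66 for the TG and FCCP ranges, 638 for TG plus ISRIB, 178 for TG plus 4μ8C, 1112 for FCCP plus 3-MA, 2273 for the TM minus FCCP response and 2852 for MG132 between TG and TM. Opposite calls were 102, 69 and 596 for ISRIB, 4μ8C and MG132 with TG and 285 for 3-MA. This step shifted the median log2 change of all genes by -0.201 to 0.182, beside -0.035 to 0.054 for RLE and for DESeq2. It moved the share of calls that were higher from 53.5% to 41% at TM 0.5 μM, 53% to 39.2% at TM 1 μM, 53.1% to 41.3% at TM 2 μM, 90.2% to 77.3% in the FCCP range, 86.4% to 53.3% for TG plus ISRIB, and from 51.1% to 36.4% and 48.3% to 36.6% for TG DMSO against TM and FCCP DMSO. In the differences of responses it moved from 44.2% to 63.1% (TG minus TM), 50% to 61.8% (TG minus FCCP) and 53.4% to 42.7% (TM minus FCCP), and for MG132 from 45.5% to 65.4% (TG minus FCCP) and 47.8% to 67% (TM minus FCCP). DESeq2 moved it from 50% to 17.6% in the TG range and 90.2% to 61.5% in the FCCP range. Among the few calls of the TG range RLE moved it from 50% to 0%, and for TM against FCCP DMSO the removal of trends moved it from 33.3% to 0%. Of 616 list medians, 6 changed sign with RLE (none with both values at least 0.1 from 0) and 52 with trends removed. In 8 of the 52 both values were at least 0.1 from 0. For TG against TM DMSO these were immediate early genes (0.43 to -0.12) and ATF4 and CHOP targets (0.16 to -0.18), for TG against FCCP DMSO degradation (0.11 to -0.21) and fatty acid genes (0.22 to -0.13), for TM against FCCP DMSO metallothioneins (-0.15 to 0.12), histones (-0.21 to 0.11) and blood and endothelial markers (-0.15 to 0.15), and at TM 1 μM fatty acid genes (0.10 to -0.13). With TM DMSO as reference the TG doses gave 6727, 6770 and 6016 genes at rising doses, and with TG DMSO as reference FCCP 5 μM gave 2039. TM 1 μM as reference gave 210, 187 and 878 genes for TM with melatonin, ISRIB and 4μ8C, with 59, 46 and 242 opposite calls. With MG132 opposite calls were 1674 for TG with TM DMSO and 903 for FCCP with TG DMSO.

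Single genes called with either reference changed sign as follows, and sign changes of genes called with neither were not counted. Values are log2 changes with the exchanged reference, past the threshold only where marked called. An exchanged DMSO group belongs to another series, so drug and series cannot be told apart in these values. With their sign kept, 21 results with TM 1 μM, 22 with TG DMSO and 5 with TM DMSO lost their call, and 0, 3 and 3 gained one. With TM DMSO, TG 2 μM gave METTL7A 1.93 (called), AKR1C3 0.13 and WNT6 0.27. With TG DMSO, TM 2 μM gave HSPD1 0.32. FCCP 1.25 μM gave ASNS 0.71, ATF5 0.65, HSPD1 0.83 and SQSTM1 1.30 (all called), FCCP 2.5 μM gave ATF4 0.08 and, called, ATF5 0.65, HSPD1 0.72 and SQSTM1 1.44. FCCP 5 μM gave ATF4 0.58, ATF5 0.80, CHORDC1 1.00 and SQSTM1 1.40 (called), and FABP5 0.08, HSP90AA1 0.47, HSPD1 0.27, MANF 0.10, MPDU1 0.26, RPS19BP1 0.23, SALL4 -0.12, UQCRB 0.08 and ZNF736 -0.04. With TM 1 μM, IMP3 was at -0.24 with melatonin and -0.07 with 4μ8C.

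Leaving out 1 library leaves its group with 1, which is assumed to vary like the other groups. It moved 25 of the 34 counts in at least 1 fit. Lowest and highest counts were 1412 and 1658 (TG 0.5 μM), 930 and 1107 (TG 1 μM), 610 and 676 (TG 2 μM), 2528 and 3280 (TM 0.5 μM), 3173 and 3590 (TM 1 μM), 1410 and 3821 (FCCP 1.25 μM), 1318 and 3254 (FCCP 2.5 μM), 1963 and 4081 (FCCP 5 μM), and 0 and 11, 685 and 1243, and 3 and 6 for the TG, TM and FCCP ranges. For modulators they were 0 and 1, 10 and 2369, and 9 and 82 (melatonin, ISRIB and 4μ8C with TG), 966 and 1179, 993 and 2917, and 1300 and 1666 (the same with TM) and 131 and 390 (3-MA). For differences they were 788 and 2002 (TM minus FCCP), 555 and 734 (melatonin), 905 and 2996 (ISRIB), 577 and 1511 (4μ8C) and 1130 and 1542 (MG132, TG minus TM), and for DMSO groups 4114 and 5825 (TG and FCCP) and 0 and 1636 (TM and FCCP). The counts of 0 come from edgeR, with 1895, 347 and 2718 genes at an unadjusted p under 0.05 with every library kept and 108, 1 and 537 in DESeq2. Opposite calls ran from 0 to 1, 2 to 7, 9 to 12 and 160 to 165 for melatonin, ISRIB, 4μ8C and MG132 with TG, 580 to 675, 569 to 697 and 641 to 772 for the first 3 with TM, and 42 to 44 and 879 to 944 for 3-MA and MG132 with FCCP. With 2 replicates at 26060229 to 38717013 counts, simulated 1.5-fold changes were recovered in 11.9% of genes in one pair of groups and 7.5% in another, so small changes in single genes are mostly missed.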

Other observations

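The SD over genes of the log2 difference between the replicates of a group was 0.49 in TG DMSO, the lowest of the 22 groups, and 0.892 in TG plus ISRIB, the highest. The next highest was 0.69 in FCCP DMSO, the reference of every FCCP dose.

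Ribosomal protein genes took 3.49% of the counts in TG plus ISRIB replicate 2 and 13.9% in FCCP DMSO replicate 1, beside 8.43% in FCCP DMSO replicate 2. Mitochondrial transcripts took 3.22% and 6.19% in these FCCP DMSO libraries, in the same order. The 20 most abundant genes took 9.54% in TM DMSO replicate 2 and 35.8% in TG plus ISRIB replicate 2.

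Groups outside the comparisons of the report were also set against each other after the data were seen. In edgeR, FCCP 2.5 μM differed from FCCP 1.25 μM in 0 genes, and DESeq2 was not run on this pair. An unadjusted p under 0.05 was found for 340 genes, fewer than unchanged genes would give. TG plus 4μ8C differed from TG plus ISRIB in 941 genes, 303 higher and 638 lower, and FCCP plus 3-MA from FCCP 1.25 μM in 1420.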
